A study of Mus musculus with 6 samples.

How the data were processed

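Whole dorsal root ganglia of lumbar levels L3 to L5 were collected from male mice and their RNA made into stranded total RNA libraries, per the labels' protocols, and sequenced as single-end reads of 75 nucleotides. The labels assigned 3 libraries to burn injury (day 3) and 3 to control. The authors deposited raw counts of whole reads per gene symbol, 1 file per library, with 38926 gene symbols. STAR, SAMtools and HTSeq, and the builds mm10 and GRCm38, are named per the submitters' processing notes, without versions. The annotation release and the strand setting of the counting are not given in the sources used here.

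Each file ended with 5 HTSeq tally lines that name no gene. They held from 49.18% of all entries in burn 2 (95% Wilson interval 49.17 to 49.19) to 56.22% in burn 1 (56.20 to 56.23) and were left out of library sizes and tests. Alignments that were not unique took the largest part, so genes with near-identical copies are undercounted. The reads carry no molecular identifiers. All 6 libraries were used. Within groups, pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom from 43.7 to 212), so no library was counted as a repeat of another.

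Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with its default minimum count of 10 and minimum total of 15, which left 17534 genes. Libraries were scaled by TMM, dispersions were estimated with estimateDisp (biological coefficient of variation 0.221), and burn was compared with control by glmQLFit with robust set and glmQLFTest, two-sided, with group as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the scaled library sizes. Intervals on pooled ratios of sparse genes are exact binomial intervals at 95%.

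Before the data were examined, 30 gene lists were fixed for the neurons, glia and other cell types of the ganglion, for neighbouring tissues and for processes. Each was tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, over lists with at least 3 tested members, adjusted over the 30 lists. A run with an estimated correlation and a run with fry were made beside it. The lists covered injury and regeneration, neuropeptides, nociceptor channels and receptors, potassium channels, pan-neuronal, large neurofilament, peptidergic and non-peptidergic neurons, satellite glia, myelinating Schwann cells, macrophages, neutrophils, lymphocytes, cytokines, acute phase, interferon response, erythroid cells, skeletal muscle, spinal cord, cartilage and bone, endothelium, mural cells, fibroblasts, adipocytes, proliferation, heat shock, clock, glucocorticoid response, immediate-early genes and cholesterol synthesis.

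The rule for named genes was also fixed beforehand. It took the called genes with the largest changes in each direction with a mean log2 CPM of at least 0 and no overlap between the groups, up to 4 called members of each list, the genes Cckbr, Atf3, Gal, Npy, Sprr1a, Trpv1, Trpa1, Scn9a, Scn10a, Calca, Tac1, Bdnf and Csf1 whatever their result, and up to 3 members with the lowest p of a list without calls. Other genes named, such as Lipn, Nts, Ecel1, Ucn, Grp, Pdyn, Flrt3, Stmn4, Gadd45a and Sox11, were chosen after their values were seen. Some items are not reported here.

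Alternatives planned beforehand were other scaling factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, an adjusted p under 0.1, a test against a log2 fold change of 0.3, removal of mitochondrial, haemoglobin and rRNA genes, a replicate block and leaving out each library. DESeq2 gave no adjusted p for 17666 of the 38926 genes. A split of the libraries by depth, found from the totals, was added after the data were seen, with a depth term, the 4 shallower libraries alone and thinning to the lowest total, as were covariates for skeletal muscle and spinal cord transcripts. The tests were tested on simulated data drawn from the means and depths of these libraries, over 17360 genes. They recovered 59.7% of 67 genes with a log2 change of 1, 94.0% of 67 with a change of 2 and 100% of 66 with a change of 4, with 16 false calls. A shifted list was called and 0 of 29 unshifted lists were. Simulated genes varied independently and the unshifted lists held random genes. The simulation therefore says nothing about false calls of lists whose members vary together, such as proliferation (estimated correlation 0.941). It also held no difference between deeper and shallower libraries beyond depth, and more genes were changed at once than passed in the data.

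Coordinates and overlaps came from GENCODE mouse release 21 on GRCm38, in which 35656 of the 38926 symbols (91.6%) were found. Figures were drawn with matplotlib 3.10.9, adding 0.1 CPM before the log.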

Results

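Stranded total RNA was sequenced from whole dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, taken at lumbar levels L3 to L5 of male C57BL/6 mice. The labels name the samples both as neurons and as whole ganglia, and the extraction they describe started from whole ganglia. There were 3 libraries from mice 3 days after a burn injury and 3 control libraries. The title of 1 burn library names it ipsilateral and gives no number; it is called burn 3 here, and the side of the other 2 is not given. The total of reads counted in genes ranged from 17273908 to 81968142 per library. Control libraries 1, 2 and 3 held 35991111, 17273908 and 81968142, and burn libraries 1, 2 and 3 held 22023565, 30074469 and 70002671. Burn 3, the library titled as ipsilateral, and control 3 lay above the widest gap in these totals, a ratio of 1.94, and the first principal component, with 39.4% of the variance, separated these 2 libraries, 1 of each group, from the other 4. They also had the highest shares of mitochondrial transcripts, 5.44% in burn 3 (95% Wilson interval 5.436 to 5.446) and 4.41% in control 3 (4.405 to 4.414), against 1.71% (1.706 to 1.719) to 2.70% (2.689 to 2.703) in the other 4. The share of 14 skeletal muscle transcripts ran from 0.0750% in control 3 (0.0744 to 0.0756) to 1.22% in control 1 (1.219 to 1.226), and both groups held high and low libraries. Intervals on shares cover counting error only. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. Counts of the Y-linked gene Ddx3y ran from 1266 to 8533 per library and counts of Xist, the X-inactivation transcript of females, from 1 to 9, so no library departed from its male label.

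The study set out to characterise, in sensory ganglia, the transcripts that accompany burn pain, and the comparison of burn with control ganglia addressed it. Transcripts known from injured sensory neurons were higher after the burn. Atf3, a stress-response transcription factor switched on in neurons with damaged axons, stood at 72.2 ± 10.8 CPM, the normalised read count per library (mean ± SD, n = 3), after the burn and 6.97 ± 0.234 in controls, a 10.3-fold rise (log2 fold change 3.37, SE 0.15, adjusted p 0.000387 by edgeR's quasi-likelihood test). Gpr151, an orphan G-protein-coupled receptor, rose 13.6-fold, from 1.08 ± 0.0641 to 14.7 ± 4.33 CPM (n = 3; edgeR adjusted p 0.00915). Npy, which encodes neuropeptide Y, a peptide nearly absent from uninjured sensory neurons, rose from 0.213 ± 0.0446 to 6.82 ± 3.35 CPM (n = 3; log2 fold change 4.94, SE 0.48, edgeR adjusted p 0.0434). Lipn, a member of the acid lipase family, had 2, 0 and 3 reads in the controls and 28, 67 and 118 after the burn (edgeR adjusted p 0.0323). The pooled ratio of Lipn was 48.2, with a 95% exact counting interval of 20.3 to 150. It fell outside the rule for named genes, being under its minimum expression, and was chosen after its values were seen.

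These 4 genes, all higher after the burn, were the ones that passed among 17534 genes tested with edgeR at an adjusted p under 0.05, and 0 genes were lower. At an unadjusted p under 0.05 there were 357 higher and 162 lower genes, and DESeq2 called 28 higher and 0 lower, limma-voom 3 higher and 0 lower. DESeq2 called all 4 of these genes, while limma-voom called Atf3, Lipn and Ucn but neither Gpr151 (adjusted p 0.0543) nor Npy (0.206). The 3 burn and 3 control values did not overlap in 1269 genes (7.24%), where chance gives 10%. On the log2 scale, Atf3 differed by 3.05 between the 2 deeper libraries and by 3.50 among the 4 shallower ones, Gpr151 by 3.22 and 3.88, Npy by 3.59 and 5.12, and Lipn by 4.43 and 4.61. With a term for depth, 38 genes were called (17 higher, 21 lower), and with the 4 shallower libraries alone 15 (11 higher, 4 lower), including these 4 genes in each case. Leaving out control 1, control 2, control 3 or burn 2 left 1 call, Atf3. Leaving out burn 1 left 3 calls, without Npy, and leaving out burn 3 gave 6, without Lipn. With the mean level of spinal cord transcripts as a covariate no gene passed in edgeR (140 higher and 394 lower at an unadjusted p under 0.05), and the lowest adjusted p was 0.0845, for Atf3.

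In GRCm38 coordinates from the GENCODE annotation, Atf3 lies on chromosome 1 at 191170296 to 191218039, Gpr151 on chromosome 18 at 42577881 to 42579652, Npy on chromosome 6 at 49822710 to 49829507, Lipn on chromosome 19 at 34067358 to 34084918 and Cckbr on chromosome 7 at 105425731 to 105470898. All 5 are protein-coding genes. Over whole gene spans, introns included, Atf3 overlaps Gm24748 on the other strand and Lipn overlaps Gm23334 on its own strand. Overlap of exons was not examined, and the strand setting of the counting is not given in the sources used here. Whether reads of an overlapping partner entered these counts is therefore not known. Other named genes with annotated overlaps include Flrt3 with Macrod2, Bdnf with Gm45346, Gadd45a with E230016M11Rik, Grp with AC152076.4, Syn1 with Araf and Timp1, Ccna2 with Exosc9, Kcnq3 with Gm27153, Gfra1 with Gm16277, Htr3a with Gm32335, Ccl2 with Gm17268, Scn9a with Gm13627 and Gm13629, Top2a with Gm26394 and Gad2 with Gm23636, and the same limit holds for them.

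Genes of the nerve injury and regeneration list rose as a group. Of 24 members 21 were tested, all 21 with a positive log2 fold change, and the median was 0.74 (camera adjusted p 3.06e-35, and adjusted p = 0.0272 with an estimated correlation). Over all genes 3 members passed in edgeR (Atf3, Gpr151 and Npy), DESeq2 called 10 and limma-voom 1, Atf3, and 12 were higher in edgeR when adjusted over the list alone. The other 9 of these 12 were Cckbr, Nts, Ecel1, Gal, Sprr1a, Flrt3, Stmn4, Gadd45a and Sox11. Gal, which encodes the neuropeptide galanin, stood at 20.01 ± 4.16 CPM after the burn and 5.99 ± 1.24 in controls (n = 3; edgeR adjusted p 0.12). Sprr1a, a small proline-rich protein linked to axon growth, had 447, 486 and 254 reads after the burn and 2, 1 and 19 in controls (edgeR adjusted p 0.196). In CPM the burn libraries 1 to 3 stood at 19.7, 16.1 and 3.86. On the log2 scale Sprr1a differed by 3.77 between the 2 deeper libraries and by 7.44 among the 4 shallower ones. Ecel1, an endopeptidase-like protein of injured neurons, had a log2 fold change of 2.86 (SE 0.34, edgeR adjusted p 0.0876). The log2 fold changes were 0.86 for Flrt3, 0.75 for Stmn4, 0.58 for Gadd45a and 0.74 for Sox11. Smaller values stood at Bdnf, a neurotrophin (0.43, SE 0.17), Csf1, a microglia-activating cytokine (0.40, SE 0.17), Cacna2d1, the calcium channel subunit bound by gabapentin (0.47), Gap43 (0.25) and Jun (0.21), none of which passed over all genes or over the list alone. Spinal cord transcripts had positive signs in the same comparison (median log2 fold change 1.27 over 10 genes), and with their mean level as a covariate the injury list had an adjusted p of 2.64e-23, upward. Mean levels of the list differed by 1.23 on the log2 scale between the 2 deeper libraries and by 1.74 among the 4 shallower ones.

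**Figure D1:**
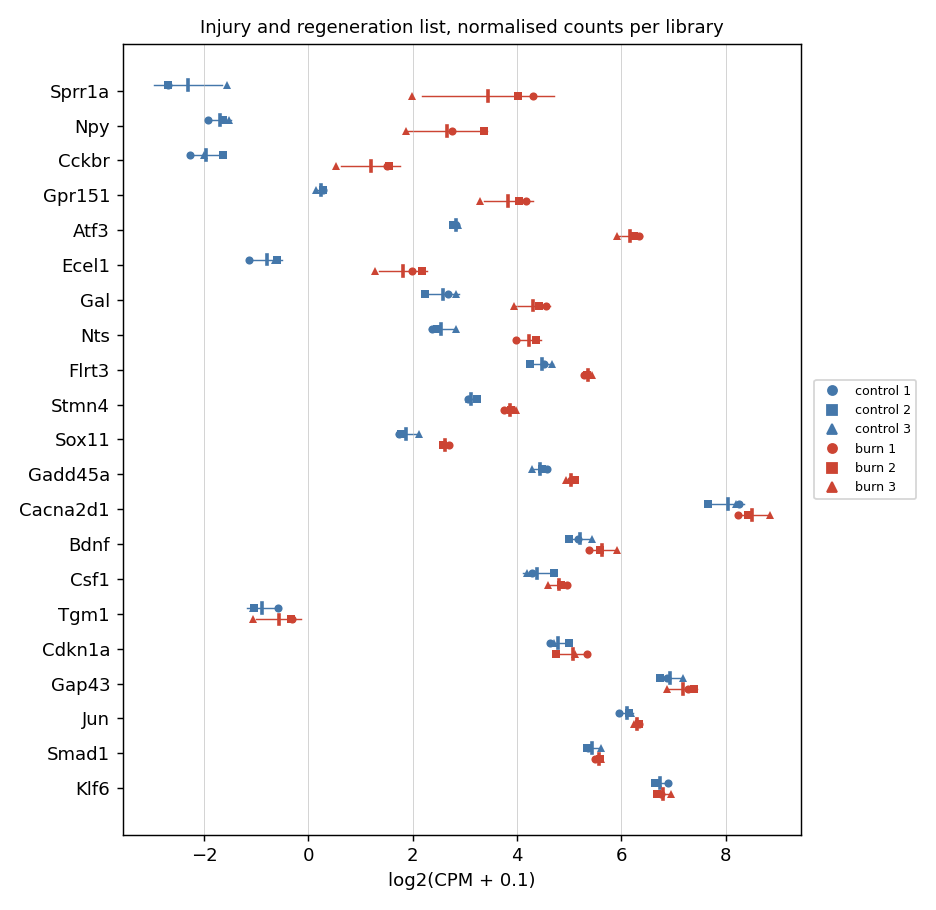
Normalised level of each tested member of the injury and regeneration list, on a horizontal axis of log2(CPM + 0.1), with 1 point per library (control in blue, burn in red, symbols for library numbers), a thick tick at the group mean and a line of 1 SD to each side (n = 3). Atf3, Gpr151 and Npy lie apart between the groups without overlap, at 72.2 against 6.97, 14.7 against 1.08 and 6.82 against 0.213 CPM.

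Cckbr, the type B receptor of the peptide cholecystokinin, stood at 2.30 ± 0.822 CPM after the burn and 0.161 ± 0.0573 in controls (n = 3), with 62, 85 and 89 reads against 4, 4 and 12. Its log2 fold change was 3.88 (SE 0.43), and it did not pass over all genes (edgeR adjusted p 0.0691), while it passed when adjusted over the list alone (adjusted p 9.92e-05). This receptor was a subject of the study itself, so its place in the list is not independent evidence. Without it the injury list had 20 tested members, 11 of them higher when adjusted over the list alone, and a median of 0.66 (camera adjusted p 3.32e-32, and adjusted p = 0.0263 with an estimated correlation). On the log2 scale Cckbr differed by 2.82 between the 2 deeper libraries and by 3.78 among the 4 shallower ones. Across 21 alternative settings its log2 fold change lay between 3.65 and 4.40, and it was called in 7 of them, 1 of which left out burn 3 (adjusted p 0.0154, in a range of 1.51e-10 to 1).

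The neuropeptide list passed upward with the preset correlation. Of 19 members 16 were tested, 10 with a positive sign, and the median log2 fold change was 0.21 (camera adjusted p 5.06e-07, and adjusted p = 0.129 with an estimated correlation). Over all genes Npy passed in edgeR, DESeq2 called 4 members (Gal, Npy, Nts and Ucn) and limma-voom 1, Ucn and not Npy. In edgeR 6 members were higher when adjusted over the list alone, Npy, Nts, Gal, Ucn, Grp and Pdyn, the first 3 of which are also in the injury list. Nts, which encodes neurotensin, stood at 18.9 ± 2.79 CPM after the burn and 5.82 ± 1.05 in controls (n = 3; edgeR adjusted p 0.0691). Ucn, which encodes urocortin, had 10, 18 and 35 reads after the burn and 0, 0 and 2 in controls, a pooled ratio of 35.6 (95% exact counting interval 9.47 to 301). Grp, which encodes gastrin-releasing peptide, had 8, 12 and 28 reads against 3, 3 and 3, and Pdyn, the precursor of dynorphin, 13, 11 and 30 against 6, 1 and 13. The main peptides of pain-sensing neurons did not pass: Calca, which encodes the calcitonin gene-related peptide, stood at 1302 ± 177 CPM against 1366 ± 64.5, and Tac1, the precursor of substance P, at 199 ± 54.7 against 206 ± 27.9 (n = 3). Beside the spinal cord transcripts, with their median of 1.27, the list had an adjusted p of 6.27e-05, upward, with their mean level as a covariate. With every library thinned to the depth of the shallowest, the list had an adjusted p of 0.0582, in a range of 2.41e-08 to 0.129 over 17 alternative settings. The list's mean level differed by 0.94 on the log2 scale between the 2 deeper libraries and by 0.91 among the 4 shallower ones.

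Ion channels and receptors of nociceptors, the pain-sensing neurons, showed no change that passed. In this list 22 of 23 members were tested, 0 were called by edgeR over all genes, 0 when adjusted over the list alone, 1 was lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. The median log2 fold change was 0.06 (camera adjusted p 0.963, and adjusted p = 0.986 with an estimated correlation). With the spinal cord transcripts as a covariate the list passed upward (adjusted p 0.00172, in a range of 0.00172 to 0.986 over 17 alternative settings). This pass used the preset correlation, while the list's estimated correlation was 0.302. No run with an estimated correlation was made with the covariate. The covariate was chosen after the data were seen, and with it 15 lists and 0 genes passed. It therefore cannot decide whether these genes rose. Trpv1, the heat and capsaicin receptor, stood at 126 ± 22.6 CPM after the burn and 127 ± 9.47 in controls (log2 fold change 0.00, SE 0.15), and its sign changed between alternative settings. Trpa1, a receptor of irritants, had a log2 fold change of 0.09 (SE 0.13). The sodium channel genes Scn9a and Scn10a had 0.11 (SE 0.26) and 0.11 (SE 0.13). The lowest unadjusted p-values of the list stood at Oprd1, the delta opioid receptor (-0.37, SE 0.12), and Htr3a, a serotonin receptor channel (-0.32, SE 0.15). In simulated counts at these depths, 59.7% of 67 genes with a log2 change of 1 and 94.0% of 67 with a change of 2 were recovered. The changed genes all had a mean of at least 1 CPM. Simulated genes varied independently, and more of them were changed at once than passed in the data. These shares may therefore be too high here. In the data Gal, at a log2 fold change of 1.72, and Ecel1, at 2.86, did not pass (edgeR adjusted p 0.12 and 0.0876). Changes of single genes of these sizes or smaller could thus pass unseen.

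Lists for the neurons and glia of the ganglion did not pass. Their median log2 fold changes were -0.10 for 12 pan-neuronal genes (adjusted p 0.368), 0.05 for 11 genes of large neurofilament neurons (0.376), -0.03 for 11 of peptidergic neurons (0.771), 0.04 for 13 of non-peptidergic neurons (0.619), 0.12 for 19 potassium channels (0.167), 0.00 for 10 of satellite glia (0.781) and -0.08 for 13 of myelinating Schwann cells (0.297), with camera's adjusted p in parentheses. The Schwann cell list passed downward without control 1 (adjusted p 0.00307) and without burn 3 (0.000166), in a range of 0.000166 to 0.972 over 17 alternative settings. The potassium channel list passed upward without control 3 (0.0029) and without burn 1 (0.00978), in a range of 0.00134 to 0.972. The pan-neuronal list passed downward without control 2 (0.0327), in a range of 0.00327 to 0.972, and upward with the spinal cord covariate (0.00327), and the large neurofilament list passed upward without control 3 (0.0379), in a range of 0.00553 to 0.972. These passes used the preset correlation of 0.01. With an estimated correlation, over all libraries, the Schwann cell, potassium channel, pan-neuronal and large neurofilament lists each had a camera adjusted p of 0.966. Gfra1, a GDNF co-receptor, had a log2 fold change of 0.42 (SE 0.11), and Kcnq3, a subunit of the M-type potassium channel, 0.60 (SE 0.18), neither of which passed (edgeR adjusted p 0.9998 for both). Syn1, which encodes a synaptic vesicle protein, had 0.46 (SE 0.16), and Apoe, abundant in satellite glia, -0.28 (SE 0.16).

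Immune and inflammatory lists did not pass either. The median was 0.20 for 16 macrophage genes (camera adjusted p 0.123), -0.27 for 13 neutrophil genes (0.104), -0.34 for 10 tested genes of T and B lymphocytes (0.104), 0.42 for 10 tested cytokines and chemokines (0.123), 0.05 for 15 acute-phase genes (0.321) and 0.08 for 15 interferon-response genes (0.243). Ccl2, a monocyte chemoattractant, stood at 2.72 ± 0.255 CPM after the burn and 1.57 ± 0.487 in controls (n = 3; log2 fold change 0.76, SE 0.27, edgeR adjusted p 0.9998). Il6 had 11, 17 and 34 reads against 12, 2 and 18 in libraries of unequal depth. In CPM it stood at 0.522 ± 0.0388 against 0.222 ± 0.108 (n = 3), with a log2 fold change of 1.14 (SE 0.37, edgeR adjusted p 0.9998). The direction of the macrophage list turned without control 3 or burn 1, and that of the neutrophil list without burn 3. The macrophage list passed without control 1 (adjusted p 0.0118) and without burn 3 (5.32e-06), and with the depth term (0.0381), in a range of 5.32e-06 to 0.972 over 17 alternative settings. The neutrophil list passed without control 3, burn 1 or burn 2, at adjusted p 6.32e-06, 0.00654 and 0.0126, and with the depth term at 1.33e-06, in a range of 1.33e-06 to 0.972. The lymphocyte list passed downward in 7 of its 17 alternatives, among them without control 3 (0.000117), without burn 1 (0.000489) and with the depth term (0.0381), in a range of 0.000117 to 0.972. Without burn 3 the cytokine list (0.0236, in a range of 0.0236 to 0.914) and the acute-phase list (0.024, in a range of 0.024 to 0.991) passed upward. These passes used the preset correlation of 0.01. The estimated correlation was 0.899 for macrophage, 0.958 for neutrophil and 0.634 for lymphocyte genes. With it, over all libraries, each of those lists had a camera adjusted p of 0.966.

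Of the lists for tissues next to the ganglion, spinal cord and cartilage and bone passed, and skeletal muscle (camera adjusted p 0.808) and adipocytes (0.877) did not. The spinal cord list passed upward with the preset correlation: all 10 list members had a positive log2 fold change, with a median of 1.27 (camera adjusted p 2.67e-12, and adjusted p = 0.394 with an estimated correlation and 0.454 by fry). Over all genes 0 passed in edgeR and 6 were higher when adjusted over the list alone, 9 were higher at an unadjusted p under 0.05, DESeq2 called 1, Gad2, and limma-voom 0. With the depth term DESeq2 called Gad2 and Mog. Gad2, an enzyme of inhibitory neurons, stood at 2.43 ± 0.975 CPM after the burn and 0.632 ± 0.272 in controls (n = 3), and the oligodendrocyte genes Opalin and Hapln2 had log2 fold changes of 2.18 (SE 0.55) and 1.23 (SE 0.34). The list's share of reads in burn 2, 0.01011% (95% Wilson interval 0.009755 to 0.01047), lay within the range of the controls, whose highest was 0.0102% in control 2 (0.009735 to 0.01069). The list's mean level was 2.80, 1.86 and 2.83 in burn libraries 1 to 3 and 1.61, 1.53 and 0.62 in control libraries 1 to 3, on a log2 CPM scale. It differed by 2.21 between the 2 deeper libraries and by 0.76 among the 4 shallower ones.

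Proliferation genes passed downward as a list: all 12 had a negative log2 fold change, with a median of -0.66 (camera adjusted p 8.28e-08, and adjusted p = 0.728 with an estimated correlation), and 0 passed in edgeR over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 lower members, and DESeq2 and limma-voom called 0. With the depth term DESeq2 called Ccna2, Ccnb2, Cdk1, Cenpf, Kif11, Mki67 and Top2a. Ccna2, a cyclin, stood at 13.8 ± 2.92 CPM after the burn and 23.7 ± 8.56 in controls (n = 3), and Top2a, a DNA topoisomerase, at 41.7 ± 12.8 against 67.5 ± 23.7. The list differed by -0.42 between the 2 deeper libraries and by -0.70 among the 4 shallower ones. Cartilage and bone genes passed downward as a list too, with a negative sign in 9 of 10 tested members and a median of -0.72 (camera adjusted p 1.86e-06, and adjusted p = 0.33 with an estimated correlation). Over all genes 0 members passed in edgeR, DESeq2 or limma-voom, and 3 were lower at an unadjusted p under 0.05. Comp, a cartilage matrix protein, was the 1 member to pass when adjusted over the list alone, at 16.6 ± 1.75 CPM against 27.9 ± 6.30 (n = 3), and the list differed by -0.41 between the 2 deeper libraries and by -0.78 among the 4 shallower ones. Erythroid genes passed downward as a list with a median of -0.32, all 8 tested members having a negative sign (camera adjusted p 0.0119, and adjusted p = 0.966 with an estimated correlation), while 0 members passed in edgeR over all genes or over the list alone, or in DESeq2 or limma-voom, and 1 was lower at an unadjusted p under 0.05. That call ended without control 1 (camera adjusted p 0.173), control 2 (0.248) or burn 2 (0.234), in a range of 2.59e-10 to 0.972. It also ended with mitochondrial, haemoglobin and rRNA genes removed (0.104), a step that took the globin genes out of the erythroid list itself. The erythroid list differed by 0.23 between the 2 deeper libraries and by -0.64 among the 4 shallower ones. With the spinal cord covariate the proliferation, cartilage and bone, and erythroid lists had camera adjusted p of 5.64e-08, 1.23e-05 and 2.59e-10, all downward. These values used the preset correlation of 0.01, while the estimated correlations of the 3 lists were 0.941, 0.2 and 0.855. No run with an estimated correlation was made with the covariate. DESeq2 with the depth term called Bglap, Bglap2 and Comp of the bone list and Slc4a1 of the erythroid list. The globin genes have near-identical copies, as have Bglap and Bglap2 of the bone list, so their counts are uncertain.

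**Figure D2:**
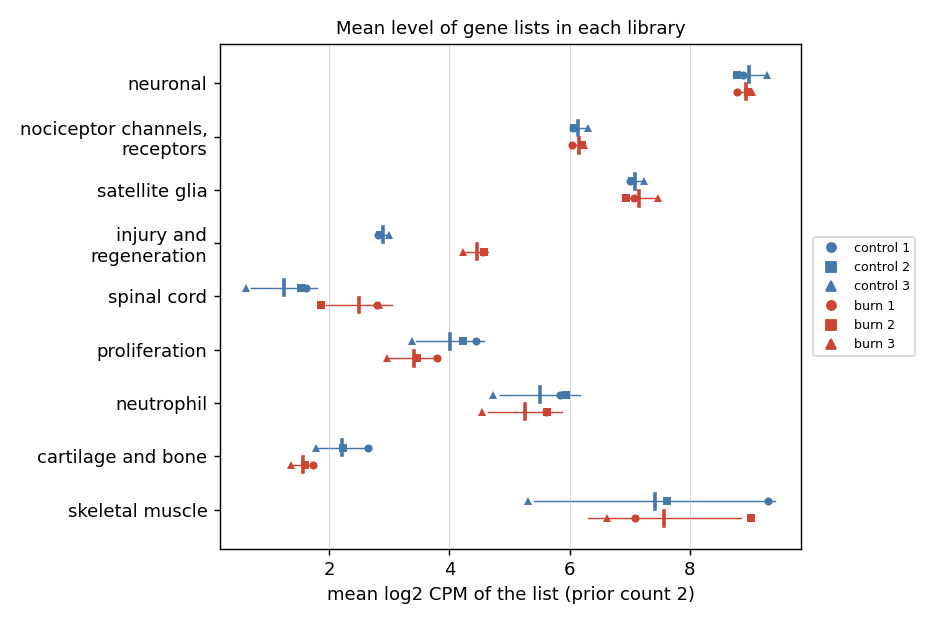
Mean log2 CPM (horizontal axis, prior count 2) of 9 gene lists in each library, with 1 point per library (control in blue, burn in red, symbols for library numbers), a thick tick at the group mean and a line of 1 SD to each side (n = 3). The injury list lies at 4.56, 4.58 and 4.23 in the burn libraries and at 2.82, 2.84 and 3.002 in the controls, while the skeletal muscle list runs from 5.31 to 9.30 within the controls.

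The remaining lists of cell types and processes did not pass. Their medians were -0.03 for 11 endothelial genes (camera adjusted p 0.771), -0.13 for 9 mural genes (0.167), -0.16 for 12 fibroblast and matrix genes (0.373), 0.23 for 9 adipocyte genes (0.877), -0.09 for 12 genes of heat shock and the unfolded protein response (0.123), 0.32 for 13 clock genes (0.101), 0.01 for 15 glucocorticoid-response genes (0.607), -0.05 for 13 immediate-early genes (0.759) and -0.01 for 14 genes of cholesterol synthesis (0.759). Skeletal muscle genes had a median of -0.09 and a mean of -0.20, while camera gave them an upward direction (adjusted p 0.808), the 1 list whose median, mean and test differed in sign. Their mean level was 9.30, 7.63 and 5.31 in control libraries 1 to 3 and 7.09, 9.03 and 6.62 in burn libraries 1 to 3. The muscle list passed upward without control 1 (0.000761) and downward without control 3 (0.00343), in a range of 0.000761 to 0.972 over 17 alternative settings, and the adipocyte list passed upward without burn 2 (0.000452) and downward without burn 3 (0.0286), in a range of 0.000452 to 0.998. The mural and fibroblast lists passed downward without control 3 (0.0247 and 0.019) or burn 1 (0.0313 and 0.00109), in ranges of 0.00133 to 0.972 and 6.27e-05 to 0.972. The clock list passed upward without control 2 (0.0319) or burn 1 (0.0316), in a range of 0.0237 to 0.93. The heat shock list passed downward without control 2 (0.0479, in a range of 0.0479 to 0.972), and the immediate-early list downward without burn 1 (0.0316, in a range of 0.0316 to 0.972). Of the 30 lists tested 6 passed, 3 upward and 3 downward. With an estimated correlation 1 passed, the injury list, and by fry 2 passed, the injury list (adjusted p 0.00235) and the neuropeptide list (0.0147).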

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

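The depth term, the 4 shallower libraries, thinning, the muscle and spinal cord covariates, robust dispersions and the depth term in DESeq2 and limma-voom were chosen after seeing the data. Genes called numbered 4 (4 higher, 0 lower), and the same 4 were called with size factors, upper-quartile factors, a test against a log2 fold change of 0.3, removal of mitochondrial, haemoglobin and rRNA genes, robust dispersions or the muscle covariate. Limma-voom called 3 (Atf3, Lipn and Ucn) and thinning 3 (all but Lipn). They were 14 (14 higher) with no filter, 2 (2 higher) with at least 10 counts in every library, 28 (28 higher) with DESeq2, 7 (7 higher) at an adjusted p under 0.1, 8 (8 higher) with limma-voom and the depth term, 38 (17 higher, 21 lower) with the depth term, 15 (11 higher, 4 lower) with the 4 shallower libraries, 146 (51 higher, 95 lower) with DESeq2 and the depth term, and 0 (0 higher) with the spinal cord covariate. Leaving out 1 library gave 1 to 6, all higher. Atf3 was called in 21 of its 22 alternatives, with a log2 fold change from 3.28 to 3.52. Gpr151 was called in 16 of 22, Npy in 14 of 21 and Lipn in 13 of 21. Lists called numbered 6, and 14 with the replicate block, 12 with the 4 shallower libraries, 15 with the spinal cord covariate, 1 with an estimated correlation and 2 with fry, and 7 to 13 when 1 library was left out (9 with the depth term). The injury list was called in all 17 of its alternatives, with adjusted p up to 0.0272. A replicate block on the libraries numbered 1 and 2 gave 4 genes (3 shared), and their deviations correlated at -0.385 over 2 pairs, which gave no sign that the numbers pair the libraries. The cause of these moves was not tested, except that fewer samples or genes enter the reduced fits and that the looser threshold admits more genes.

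No gene or list called in the comparison turned its sign, but 3 lists not called there passed in opposite directions under different settings: skeletal muscle, adipocyte and pan-neuronal genes. Trpv1 stood at 0.0027 with size factors, 0.0079 with at least 10 counts in every library, 0.014 with the 4 shallower libraries, 0.00047 with the muscle covariate, 0.277 with the spinal cord covariate, and -0.0957 to 0.136 when a library was left out. Calca stood at 0.0030 with the spinal cord covariate. With a library left out Calca ran from -0.125 to 0.038, Tac1 from -0.275 to 0.111 and Scn9a from -0.164 to 0.319. The nociceptor list turned with adjusted p 0.805 (no filter), 0.916 (limma-voom), 0.976 (thinning) and ran from 0.0716 to 0.736 with a library left out. The macrophage list turned at 0.169 (spinal cord covariate) and ran from 5.32e-06 to 0.777, and the neutrophil list from 6.32e-06 to 0.773, with a library left out. Over the alternatives of 39 chosen genes 752 values kept sign and side of the threshold, 49 passed newly, 22 lost the call and 13 turned sign. Over all 30 lists, lists not called in the comparison passed in 57 of 509 pairs of list and setting, called ones lost the call in 14, and the direction turned in 68. Depth limits genes such as Ucn, Lipn and Grp, with 9 or fewer control reads in all.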

Other observations

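The tests of the deeper libraries as a source and of satellite glia were chosen only after the results they bear on were seen, as were the depth term and the spinal cord covariate, and the reading of the test of dividing ganglion cells was changed to undecided after its value was seen. With the depth term, 21 genes were lower after the burn, none of which passed over the 6 libraries without it, while Col11a2, Hemgn and Ctse also passed in the 4 shallower libraries alone (adjusted p 0.0134, 0.044 and 0.0492). Of these, 15 were replication-dependent histone genes of the Hist1 cluster, whose near-identical copies make single counts uncertain, such as Hist1h3a (log2 fold change -1.07, SE 0.14, edgeR adjusted p 0.0379). Over all 56 tested histone genes 55 had a negative sign without the depth term, with a median of -0.82. The eosinophil granule genes Prg2, Epx and Ear6 were lower too, at -0.88 (SE 0.12), -0.92 (SE 0.13) and -1.06 (SE 0.15), as were the erythroid gene Hemgn, the protease gene Ctse and the cartilage collagen Col11a2 (-1.27, SE 0.14). Prg2 stood at 45.4 ± 19.6 CPM after the burn and 86.4 ± 42.6 in controls (SD, n = 3), and differed by -0.70 on the log2 scale between the 2 deeper libraries and by -0.97 among the 4 shallower ones. Among the 17 genes higher with the depth term were Star, which carries cholesterol into mitochondria (1.63, SE 0.23), Sema6a, an axon guidance protein (1.15, SE 0.17), and Fst, an activin antagonist (0.87, SE 0.14).

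The 7 genes with adjusted p under 0.1 (Atf3, Gpr151, Npy, Lipn, Nts, Cckbr and Ecel1) had a median log2 fold change of 3.77. With spinal cord transcripts as a covariate the median was 3.89 and all 7 stayed above 0 by more than 2 SE, which argues against spinal cord tissue as the whole source. No gene passed in that fit, in which the folds did not shrink and the median SE of the 7 went from 0.335 to 0.495; what ended the calls was not tested further. Within the 2 deeper libraries the median difference in log2 CPM was 3.05 and among the 4 shallower ones 3.78. On that same scale it was 3.46 over all 6 libraries. The 7 genes were picked on a difference over these same libraries, and the deeper pair holds 1 library of each group. The test therefore cannot decide whether the deeper libraries added to the difference. A response of sensory neurons to the burn is one hypothesis that stays open, as do unrecorded differences between the groups, and 10 splits of 6 libraries cannot give a share under 0.05: 1 of the 10 gave as many genes as the real 4, the real one itself, and the highest other gave 1.

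The spinal cord list had a median of 1.27 and passed with the preset correlation, but not with an estimated one (adjusted p = 0.394) or by fry (0.454), and 0 members passed over all genes in edgeR. DESeq2 called 1 member, Gad2, and with the depth term it called Gad2 and Mog. A second list of 12 spinal cord genes, written before its values were seen, had a median of 1.3 over 11 tested members, 5 of them at 1 CPM or more in every control, as were 5 of the first list's 10, and its mean followed the first list over the 6 libraries (Pearson r 0.957, exact permutation p 0.00694; Spearman rho 0.943, exact permutation p 0.0167; Benjamini-Hochberg adjusted over 2 relations 0.00694 and 0.0167). The r was 0.872 without the 2 libraries farthest from the median and 0.876 within groups. Spinal cord tissue carried over in unequal amounts is therefore a candidate explanation. Mobp, an abundant member of the first list, stood at 75.8 ± 28.0 CPM against 39.4 ± 17.7 (n = 3). On the log2 scale Mobp differed by 2.40 between the 2 deeper libraries and by 0.29 among the shallower ones. Its difference thus lay mainly in the deeper pair, which holds 1 library of each group. The median of the satellite glia list was 0.00458, which lies below 1.27 by more than the SD of its members, 0.232. These values argue against a change in the amount of satellite glia as the source. They cannot decide whether satellite glia changed in state, because Gfap, a glial gene, stood in the spinal cord list and not in theirs. Gfap had a log2 fold change of 1.49 (SE 0.52), and its source was not tested. A change of the burn group's own ganglia toward spinal cord transcripts was not tested.

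The proliferation list had a median of -0.662 and passed with the preset correlation, but not with an estimated one (adjusted p = 0.728), and 0 members passed in edgeR over all genes or over the list alone. DESeq2 with the depth term called Ccna2, Ccnb2, Cdk1, Cenpf, Kif11, Mki67 and Top2a. A list of 15 bone marrow precursor genes, written before its values were seen, had a median of -0.599 with all 14 tested members negative, 12 of them at 1 CPM or more in every control and none in another list, and its mean followed the proliferation list (Pearson r 0.981, exact permutation p 0.00278, adjusted 0.00556; Spearman rho 0.943, exact permutation p 0.0167, adjusted 0.0167; r 0.973 without the 2 farthest libraries). Ms4a3, an abundant member, stood at 13.4 ± 2.57 CPM after the burn and 14.03 ± 3.84 in controls (n = 3), a small difference beside the list's median, and marrow carried over in unequal amounts may account for the lower values. With the marrow list as a covariate the proliferation median was -0.134, and the list mean went from -0.608 (SE 0.408) to -0.111 (SE 0.117), but that covariate followed the list at r 0.978 within groups, which fixes such a drop whatever the source. Fewer dividing cells of the ganglion itself therefore cannot be told apart from marrow here, and a difference of blood cell precursors between the groups was not tested.

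The count of lists called also varied across groupings: 9 of the 10 splits of the 6 libraries 3 against 3 gave as many lists as the real 6, the real one included, and the highest other gave 18, which may come from a structure of the samples beyond the groups or from the preset correlation of 0.01, since 1 list passed with an estimated correlation. These were not separated, and 10 splits cannot give a share under 0.05.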
